A study of Haloferax volcanii DS2 with 16 samples.

How the data were processed

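The deposited count table holds raw read counts per gene for 16 RNA-seq libraries of Haloferax volcanii, and each column was matched to its library by the title it carries. Per the labels, cells were grown at 42 °C to an optical density of 0.4, and the challenged cultures then received 2 mM hydrogen peroxide for 1 h. Per the labels, ribosomal RNA was depleted from total RNA, and strand-specific libraries were read on an Illumina instrument. The authors counted reads with featureCounts by strand and without reads that map to several places. The aligner, its version and the genome build are not stated, nor is which medium or read layout each library had.

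The authors' workbook adds DESeq2 columns for the knockout against wild type under peroxide: the mean signal over libraries, the log2 fold change and its standard error, the Wald statistic as a score, and p values before and after adjustment. These deposited values were compared with the fits here and were not tested again. The authors also list 46 putative targets with log2 fold changes, of which 45 are in the count table, and 25 genes predicted with IntaRNA. Gene symbols came from a reference table of the assembly GCF_000025685.1 ASM2568v1. Function text exists for only 69 of the 3944 genes, and 478 have a symbol.

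The 16 libraries form 4 groups: H53 wild type without challenge (n = 4), H53 wild type with peroxide (n = 5), the H53 SHOxi knockout with peroxide (n = 4) and the H98 SHOxi knockout with peroxide (n = 3). Replicates 1 to 3 of both wild-type groups come from an earlier series per the labels, and the other 10 libraries do not. An additive term for this origin stands in the model. All knockout libraries are among the other 10. In both contrasts of a knockout with the wild type this term therefore gives replicates 4 and 5 with peroxide more weight than replicates 1 to 3. No column was left out of the fit.

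Counts were filtered with filterByExpr, which kept 3813 genes, and scaled with TMM. They were fitted in 1 model with edgeR's quasi-likelihood test, two-sided, and p was adjusted over all genes by Benjamini and Hochberg at a threshold of 0.05. The contrasts were peroxide against no challenge in the wild type, each knockout against the wild type under peroxide, and the H98 knockout against the H53 knockout. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Fold changes are fitted log2 values with their standard errors. Shares of counts between groups were compared with exact two-sided permutation tests, whose smallest possible p is 0.00794 for 5 against 4 libraries, 0.0179 for 5 against 3 and 0.0286 for 4 against 3.

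The contrasts, the model, the 22 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Of the 22 lists, 15 had fewer than 5 members because so few genes have product text, and these were not tested. The 7 tested lists were DNA repair and recombination, cobalamin biosynthesis, CRISPR-Cas, solute transporters, transcriptional regulators, the authors' putative targets and the IntaRNA predictions. All 13 transporters are known only through the function text in the authors' sheets. A further 19 lists of gene symbols and the list of tRNA genes were written later, after the first fits but before any list was tested. The lists were tested with camera at a preset correlation of 0.01, two-sided, with p adjusted over the lists of each kind, and again with an estimated correlation and with fry.

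Genes were named by a fixed rule. It takes the 10 largest rises and falls with a symbol or function text in each of the first 3 contrasts and 6 each way in the fourth, at a mean log2 CPM of at least 4. It adds up to 4 members of each tested list with the smallest adjusted p, the deleted genes, the malic enzyme, and up to 15 putative targets. A gene named outside the rule is said to be chosen after its values were seen.

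Same-numbered libraries of the wild type with and without peroxide deviate together from their group means. The correlations of the 4 pairs are 0.51, 0.66, 0.60 and 0.39, so the numbers pair the samples in this contrast by the rule fixed for it. Replicate 4 with peroxide correlates better with unchallenged replicate 1 (0.56) than with its own number. The pairing comes from the data alone, since the labels do not say that a number marks a shared day. With the genes of 1 pHV4 stretch left out, described below, the correlations are 0.04, 0.24, 0.22 and -0.09. The fit with the replicate number as a block is given beside a result only where it changes the call. Replicon shares were also compared within the 4 pairs by exact two-sided sign flips, and lists with the block also with an estimated correlation, both chosen after the data were seen, as were replicon shares over coding genes alone.

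The method was tested on simulated data made from these counts with 200 changed genes. Of genes changed by a log2 of 1 it recovered 69.7% in the peroxide contrast, 46.5% for the H53 knockout, 43.8% for the H98 knockout and 59.8% between the knockouts. At a log2 of 2 these were 91.7%, 90.7%, 92.7% and 96.9%. False calls made up 1.88%, 2.19%, 7.09% and 3.80% of all calls.

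Contrasts that share the wild-type libraries under peroxide move together even where nothing changed. Overlaps between contrasts are therefore given beside the number expected from the sizes of both calls, and beside a split of the shared libraries. The correlation and covariance of both contrasts over all genes are set beside 20 simulations of unchanged groups. Library labels were also permuted, in up to 100 splits per contrast, to see how many genes other groupings of the same libraries call.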

Results

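Cells of Haloferax volcanii were compared with and without hydrogen peroxide, and with and without the small RNA SHOxi under peroxide. The wild type and 1 knockout share the parent strain H53, which lacks pyrE2 and trpA. The second knockout stands in the parent H98, which lacks pyrE2 and a thymidylate gene, and no H98 wild type was sequenced. Any difference between the H98 knockout and the other groups therefore carries the parent strain along with the deletion. Nothing in the labels says that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

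The count totals of the wild type without challenge are 8080733, 7471755, 10551948 and 6866202 for replicates 1 to 4. The wild type with peroxide has 12600795, 7769364, 7694898, 7452550 and 13037318. The H53 knockout has 12707262, 12744032, 7000423 and 12731940, and the H98 knockout has 7426079, 7949874 and 7255634. Most of these counts are ribosomal RNA in the H53 groups. The mean share is 82.6% (SD 18.0, n = 4) without challenge, 71.3% (SD 7.39, n = 5) with peroxide and 71.2% (SD 20.9, n = 4) in the H53 knockout, but 18.8% (SD 6.43, n = 3) in the H98 knockout. Coding genes take 13.1%, 18.6%, 10.6% and 56.4% in the same order. The ribosomal genes HVO_RS13025 and HVO_RS18910, both 2913 bases long, are counted nearly alike in the H53 libraries, as 1215611 and 1219567 in replicate 1 without challenge. In replicate 1 of the H98 knockout they have 266382 and 49377. Reads that fit several copies may be counted otherwise in the H98 libraries, which was not tested. Their ribosomal, coding and tRNA shares may therefore not compare with those of the others. The tRNA genes have 81.3 counts per 1000 coding counts without challenge (SD 24.7), 139 with peroxide (SD 76.9), 1729 in the H53 knockout (SD 1177) and 93.7 in the H98 knockout (SD 38.6). The H53 knockout differs from the wild type under peroxide at an exact two-sided permutation p of 0.00794, the smallest possible, and an adjusted p of 0.0714 over 16 such tests.

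**Figure D1:**
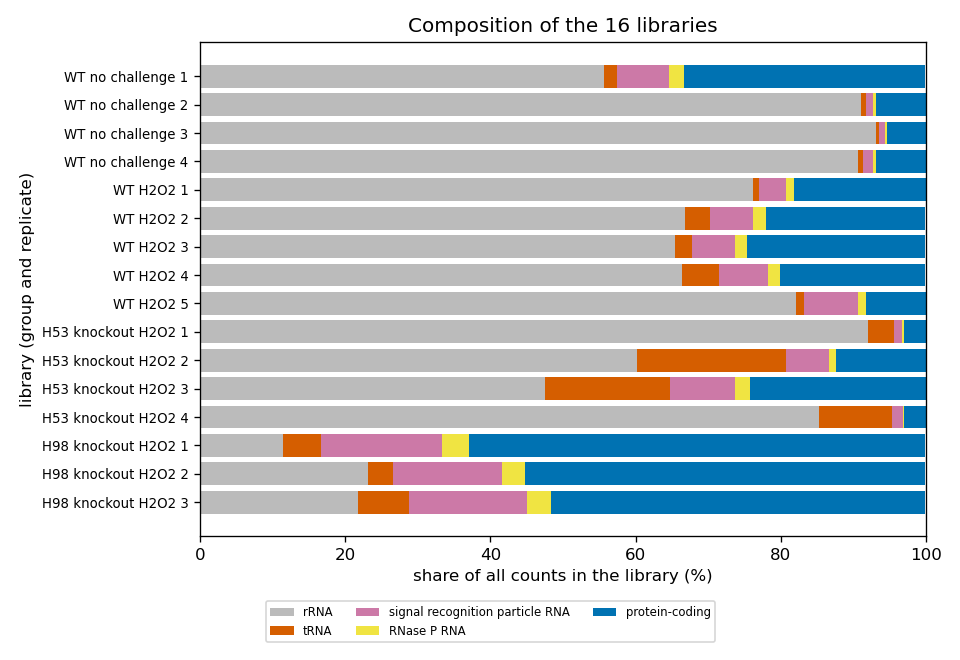
Make-up of the counts in each of the 16 libraries, as stacked percentages of all counts: ribosomal RNA, tRNA, signal recognition particle RNA, RNase P RNA and coding genes. Ribosomal RNA averages 18.8% in the H98 knockout (n = 3) and 71.2% in the H53 knockout (n = 4); tRNA takes 3.49% to 20.5% in the H53 knockout libraries and at most 7.02% in the others.

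The deleted genes were read first, as a check of the labels. The gene pyrE, the locus of pyrE2, has 0 to 7 counts in every library. The tryptophan synthase gene trpA has 1 to 11 counts in the H53 libraries and 486 to 792 in the H98 libraries. HVO_RS18820, the neighbour of thyA at the deleted thymidylate locus, has 6 to 69 counts in the H53 libraries and 0 to 1 in the H98 libraries, while thyA itself is counted in all (18 to 384). The strain labels hold by these genes. SHOxi has no entry in the count table, so its deletion could not be read from the counts.

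In a stretch of 97 neighbouring genes on the plasmid pHV4, 79 lie under 0.1 of their level elsewhere in 8 of the 16 libraries: replicates 2 and 3 of the wild type without challenge, replicates 2 and 3 with peroxide, and all 4 H53 knockout libraries. In those 8 at least 46.4% of the stretch genes have 0 counts, and in the other 8 at most 2.06% do. The median expected count per gene and library in the 8 is 30.4, and the observed median is 0. Some genes of the stretch are still counted, as HVO_RS02240 is at a mean CPM of 50.9 in the 8 and 61.1 in the others. These 8 and 8 are samples defined from the data, so the difference between them was not tested.

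**Figure D2:**
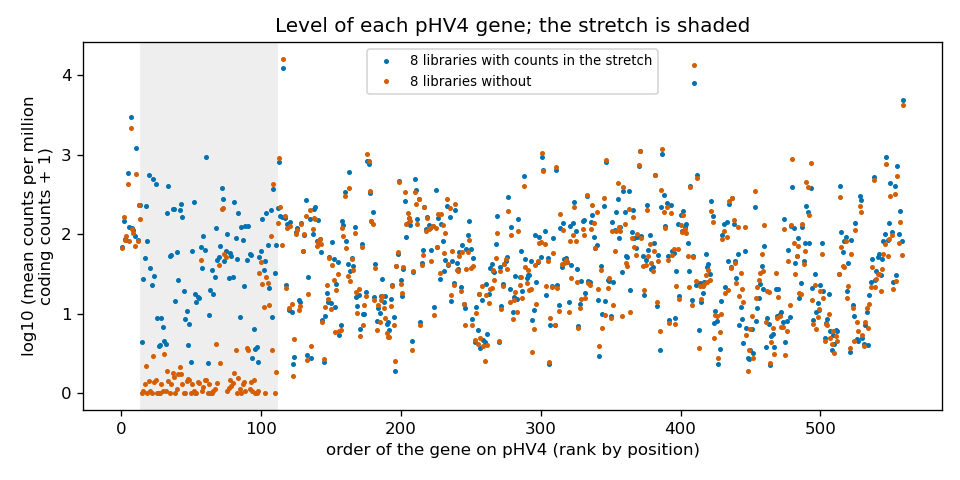
Mean CPM of coding counts (log10, plus 1) of the genes of pHV4 in their order on the plasmid, for the 8 libraries with few counts in the stretch and the other 8. The shaded region is the stretch of 97 genes. Outside it the median ratio between the libraries is 0.884 over 417 genes.

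In the wild type, peroxide raised 772 genes and lowered 735 of the 3813 tested (edgeR, adjusted p, n = 5 and 4). Genes that rose include radA, the archaeal recombinase (log2 fold change 3.26 ± 0.24 SE, adjusted p = 1.49e-07), paaA of phenylacetate breakdown (3.13 ± 0.23, 1.69e-07) and dpsA, which encodes a DNA-protecting ferritin-like protein (3.08 ± 0.25, 4.03e-07). The transcription initiation factor IIB 2 gene HVO_RS09745 rose by 2.77 ± 0.21, and the catalase-peroxidase gene katG by 2.52 ± 0.21. Genes that fell include the sugar ABC transporter gene HVO_RS03105 (-1.96 ± 0.20), the methylmalonyl-CoA carboxyltransferase gene HVO_RS16615 (-1.85 ± 0.13) and pccA (-1.79 ± 0.16), named carbamoyl phosphate synthase in the authors' sheet. Some genes without function text changed more, and these were chosen after their values were seen: HVO_RS12485 rose by 6.75 ± 0.31, HVO_RS10725 by 4.90 and HVO_RS14625 by 4.49.

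Genes that remove oxidants or repair oxidised protein rose together: 9 of 9 members of the antioxidant list were higher (camera adjusted p = 2.76e-07; adjusted p = 0.0508 with an estimated correlation). Besides dpsA and katG these include the superoxide dismutase gene sod (1.72 ± 0.27, adjusted p = 8.96e-05) and the methionine sulfoxide reductase gene msrA (1.01 ± 0.13). In iron-sulfur cluster assembly 3 of 4 genes rose, sufU (1.81 ± 0.16), sufD (1.28 ± 0.22) and sufS (1.04 ± 0.18), at a camera adjusted p of 0.00353 (adjusted p = 0.163 with an estimated correlation). The fourth, sufB, was 0.81 ± 0.34 (adjusted p = 0.0694), and 1.04 (0.000224) with the replicate number as a block; over its 27 alternatives the adjusted p runs from 0.000185 to 0.901. Of 15 proteasome, protease and chaperone genes 10 rose and 2 fell (0.00018; adjusted p = 0.291 with an estimated correlation). They include the small heat shock gene hsp14 (2.07 ± 0.17), the proteasome genes pan2 (1.60 ± 0.14) and psmB (1.37 ± 0.15) and the membrane protease gene htpX (1.42 ± 0.13).

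Breakdown of phenylacetate and histidine rose in 8 of 10 genes (camera adjusted p = 5.4e-05; adjusted p = 0.126 with an estimated correlation). The histidine genes hutU (2.29 ± 0.24), hutG (2.05 ± 0.34) and hutI (1.99 ± 0.24) lie side by side, as do the paa genes. Sugar and glycerol uptake and breakdown rose in 10 of 27 genes (0.0218; adjusted p = 0.303 with an estimated correlation). Examples are glpA (2.17 ± 0.27), dgoD at HVO_RS03025 (1.98 ± 0.25), dgoD at HVO_RS03335 (1.42 ± 0.16) and the fructose phosphotransferase gene ptfB (1.66 ± 0.25). The tubulin-like gene cetZ3 rose as well (2.16 ± 0.26). The tRNA list had 2 of 53 genes higher, with a median log2 fold change of 0.71 (0.112, and 0.000547 with the replicate number as a block; adjusted p = 0.802 and 0.609 with an estimated correlation).

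Cobalamin synthesis fell. In the list built from product text 4 of 5 genes were lower, and 5 when p was adjusted over the list alone (camera adjusted p = 0.00548; adjusted p = 0.148 with an estimated correlation). In the wider list of symbols 8 of 12 were lower (0.00018; adjusted p = 0.126 with an estimated correlation), among them cobM (-1.56 ± 0.28), cobN (-1.53 ± 0.17), cobJ (-1.04 ± 0.18), cbiT (-1.01 ± 0.17) and cbiG (-0.96 ± 0.14). The gene cbiB was lower at -0.85 ± 0.25, and at -0.71 without replicate 4 of the unchallenged wild type, which ends its call. Of 13 solute transporters 7 fell and 1 rose, and 8 fell and 1 rose over the list alone (0.000433; adjusted p = 0.117 with an estimated correlation). HVO_RS07265 (-1.69 ± 0.20) and HVO_RS07270 (-1.78 ± 0.22) encode neighbouring ABC permeases, which fell with the sugar permease gene HVO_RS17705. The TCA and glyoxylate list had 6 of 9 genes lower and 1 higher (0.0277; adjusted p = 0.126 with an estimated correlation), with aceB (-0.94 ± 0.19), sucD (-0.91 ± 0.16), sucC (-0.89 ± 0.16) and icd (-0.62 ± 0.15). The malic enzyme gene HVO_RS16435 fell by 0.98 ± 0.17 (0.000248).

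Nucleotide synthesis had 11 of 23 genes lower and 1 higher (camera adjusted p = 0.00879; adjusted p = 0.208 with an estimated correlation). The genes purQ (-1.22 ± 0.16), carB (-1.17 ± 0.13) and carA (-1.04 ± 0.12) fell, and guaB rose (0.86 ± 0.14). Both gdhB genes of glutamate dehydrogenase fell, at HVO_RS11705 (-1.78 ± 0.21) and HVO_RS01295 (-1.58 ± 0.19), as did hmgB of the mevalonate pathway (-1.35 ± 0.15) and the aminotransferase gene HVO_RS00335 (-1.79 ± 0.17). Amino acid synthesis had 14 of 43 higher and 4 lower (0.0938, and 0.0103 with the replicate number as a block; adjusted p = 0.669 and 0.240 with an estimated correlation), and 6 of 15 aminoacyl-tRNA synthetase genes were lower and 1 higher (0.0922).

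Product-text lists that did not pass camera in the peroxide contrast were DNA repair, with 4 of 10 higher and 3 lower (adjusted p = 0.491), CRISPR-Cas, with 2 of 7 higher (0.491), and regulators, with 5 of 10 higher and 3 lower (0.204); all 3 have the same counts over the list alone. Single members still rose: cas6, the CRISPR RNA endonuclease (1.34 ± 0.15), cas7b (0.46 ± 0.16, adjusted p = 0.0355, from 0.00195 to 0.809 over 27 alternatives), the double-strand break gene mre11 (1.01 ± 0.20), lrpA1 (1.09 ± 0.18), the ArsR regulator HVO_RS08400 (2.03 ± 0.29), the ArcR regulator HVO_RS19590 (2.02 ± 0.29) and the TrmB regulator HVO_RS12280 (1.37 ± 0.15). The mismatch repair gene mutL at HVO_RS07350 (-0.55 ± 0.13) and the ligase gene ligA (-1.04 ± 0.19) fell. Of 25 IntaRNA predictions 4 were higher and 6 lower, and 5 and 7 over the list alone (0.491), with the quinone reductase gene HVO_RS09720 at 1.13 ± 0.17. The authors' 45 putative targets had 21 higher and 20 lower, and 21 and 24 over the list alone (0.848); that list was chosen on these samples and is not independent.

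The peroxide calls depend on scaling for composition. With library totals alone only 30 genes were higher and 1 lower, and the median coding log2 fold change is 0.38 in place of -0.05; why the calls end was not tested. With libraries that are not reanalysed alone (2 against 1) 294 were higher and 197 lower.

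In the H53 knockout under peroxide 400 genes were higher and 634 lower than in the wild type under peroxide (edgeR, adjusted p, n = 4 and 5). The ArsR regulator gene HVO_RS08400 fell by 2.65 ± 0.32 SE (log2; adjusted p = 8.94e-05). Genes that were higher include gdhB at HVO_RS11705 (2.14 ± 0.25, 8.38e-05), pccA (2.00 ± 0.19, 3.05e-05), hmgB (1.68 ± 0.19, 5.17e-05) and HVO_RS16615 (1.54 ± 0.16, 4.6e-05), each of which had fallen with peroxide in the wild type. Of the 400 higher genes 50 are tRNA genes, and of the 634 lower genes 75 lie in the pHV4 stretch and 110 elsewhere on pHV4.

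The histidine and phenylacetate genes were higher in 8 of 10 members (camera adjusted p = 4.6e-06; adjusted p = 0.098 with an estimated correlation), the same direction as with peroxide. Examples are paaD (2.44 ± 0.41), paaC (1.91 ± 0.33), hutH (1.24 ± 0.29) and hutI (1.16 ± 0.26). Solute transporters were higher in 8 of 13 genes and lower in 1, and the same over the list alone (0.000129; adjusted p = 0.0571 with an estimated correlation). The neighbours HVO_RS07260 (1.89 ± 0.26), HVO_RS07270 (1.61 ± 0.27) and HVO_RS07265 (1.47 ± 0.25) rose, as did arcD (2.42 ± 0.42), HVO_RS17705 (1.46 ± 0.29) and HVO_RS01070 (1.37 ± 0.34), and HVO_RS01525, a glucose transporter gene, was lower (-1.30 ± 0.30). The acetyl-CoA synthetase gene acs (1.44 ± 0.25), HVO_RS16620 (1.73 ± 0.29), HVO_RS00335 (1.35 ± 0.20) and the malic enzyme gene HVO_RS16435 (1.12 ± 0.20, 0.00132) rose. Of 15 aminoacyl-tRNA synthetase genes 3 rose, serS (0.78 ± 0.22), argS (0.62 ± 0.22, adjusted p = 0.0491) and alaS (0.53 ± 0.15), at a camera adjusted p of 0.0284 (2 over the list alone; adjusted p = 0.596 with an estimated correlation, and 0.314 without the term for library origin). The tRNA genes themselves were higher in 50 of 53, with a median of 3.25 (3.68e-38; adjusted p = 0.281 with an estimated correlation).

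Transcriptional regulators were lower in 5 of 10 genes and higher in 1, and lower in 6 and higher in 3 over the list alone (camera adjusted p = 0.021; adjusted p = 0.0571 with an estimated correlation). Besides HVO_RS08400 they include HVO_RS09110 (-1.51 ± 0.27), HVO_RS12280 (-1.44 ± 0.17, 8.87e-05) and lrp (-1.04 ± 0.16). The regulator gene HVO_RS19590 (-1.57 ± 0.32), the transcription factor gene HVO_RS09745 (-1.26 ± 0.22) and the nickel regulator gene nikR (-1.31 ± 0.21) fell too. N-glycosylation of surface proteins was lower in 9 of 12 genes (0.00183; adjusted p = 0.281 with an estimated correlation), among them agl10 (-1.46 ± 0.37), aglQ (-1.24 ± 0.23), aglG (-0.74 ± 0.16) and aglF (-0.72 ± 0.17). Protein export genes tatAo (-1.65 ± 0.45, adjusted p = 0.014) and secD (-1.32 ± 0.33) and the translation factor gene eif1A (-1.31 ± 0.25) fell. Genes without a known function that fell include the putative targets HVO_RS14415 (-2.40 ± 0.37), HVO_RS13640 (-1.73 ± 0.26) and HVO_RS00065 (-0.99 ± 0.16).

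The other lists did not pass camera in this contrast. Cobalamin had 0 of 5 genes past the threshold in edgeR, over all genes or the list alone, 0 at an unadjusted p and 0 in DESeq2 or limma-voom (camera adjusted p = 0.447). DNA repair had 1 of 10 higher (0.141), with ligA at 0.74 ± 0.22 (0.57 without replicate 4 of the wild type and 0.68 without replicate 1 of the knockout, which end its call), and CRISPR-Cas 1 of 7 higher and 2 lower (0.892), with the same counts over both lists alone. The last comprise cas5b (0.75 ± 0.23), cas2 (-1.68 ± 0.43) and cas1b (-0.93 ± 0.28). Of the 25 IntaRNA predictions 3 were higher and 3 lower, and 4 and 3 over the list alone (0.447). The 45 putative targets had 19 higher and 21 lower, and 21 each way over the list alone (0.447); chosen on these samples, they are not independent.

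Replicate 5 of the wild type with peroxide weighs most here: without it 233 genes are higher and 265 lower, and 465 of the 1034 calls stay, while without its replicate 4 there are 640 and 810. Without replicate 5 the calls of HVO_RS01525 (-0.86), cas5b (0.56), cas1b (-0.58), alaS (0.39), argS (0.34), tatAo (-0.12), serS (0.49), secD (-0.36) and agl10 (-0.70) end, those of cas5b (0.57), cas1b (-0.70) and tatAo (-1.43) also end without replicate 3 of the knockout, and that of argS ends without any library of either group but replicate 4 of the wild type. With library totals alone 11 genes are higher and 69 lower (median coding log2 fold change -0.23), with the pHV4 stretch as the term in place of library origin 240 and 243, with 416 calls kept and those of 11 of 45 named genes ended. With both knockouts as 1 group the calls of 14 of the 45 end, among them HVO_RS08400 (0.0354), the malic enzyme gene (0.53), paaD (1.64), hutH (0.73), hutI (0.63), hutG (0.97), acs (0.94) and HVO_RS16620 (1.06).

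**Figure D3:**
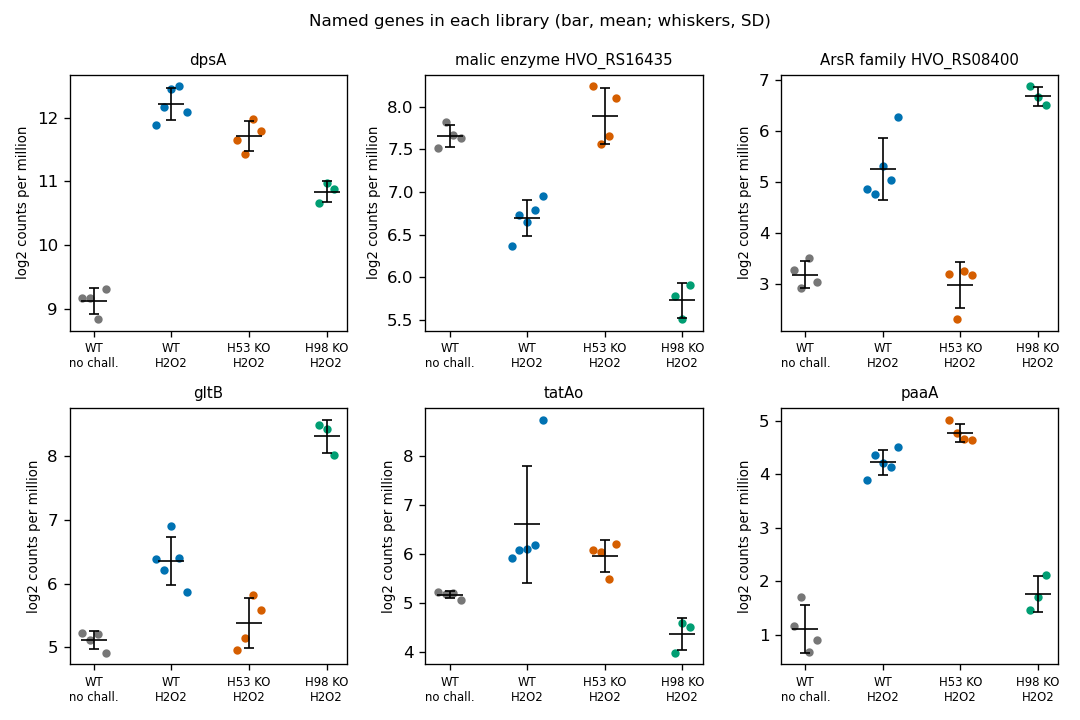
Log2 CPM in each library, with group mean and SD, for 6 named genes: dpsA, the malic enzyme gene HVO_RS16435, the ArsR regulator gene HVO_RS08400, gltB, tatAo and paaA. HVO_RS08400 lies at 2.30 to 3.25 in the H53 knockout (n = 4) and at 4.76 to 6.28 in the wild type with peroxide (n = 5). The gene tatAo lies at 8.74 in replicate 5 of the wild type with peroxide and at 5.92 to 6.19 in its other replicates.

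Genes that moved one way with peroxide and the other way in the H53 knockout were counted, since the authors chose putative targets by this converse pattern. There were 206 genes higher with peroxide and lower in the knockout, against 128 expected from the sizes of both calls, and 114 lower with peroxide and higher in the knockout, against 77.1. HVO_RS08400, HVO_RS12280, HVO_RS19590 and HVO_RS09745 are in the first set, and gdhB at HVO_RS11705, pccA, hmgB, HVO_RS16615 and the malic enzyme gene in the second. Because the same wild-type libraries stand in both contrasts, the count was repeated with those libraries split between them. It gave 167 (111 expected) and 59 (46.5 expected). Over all genes the fold changes of both contrasts correlate at r = -0.0363 with a covariance of -0.0405, against -0.220 and -0.0310 in simulated unchanged groups that share libraries. With the libraries split, r is -0.0923 and the covariance -0.0666. Without replicate 5 of the wild type with peroxide the first count is 122, and without its replicate 4 the second is 213. With library totals alone both counts are 0 in edgeR, and 9 and 0 at an unadjusted p.

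**Figure D4:**
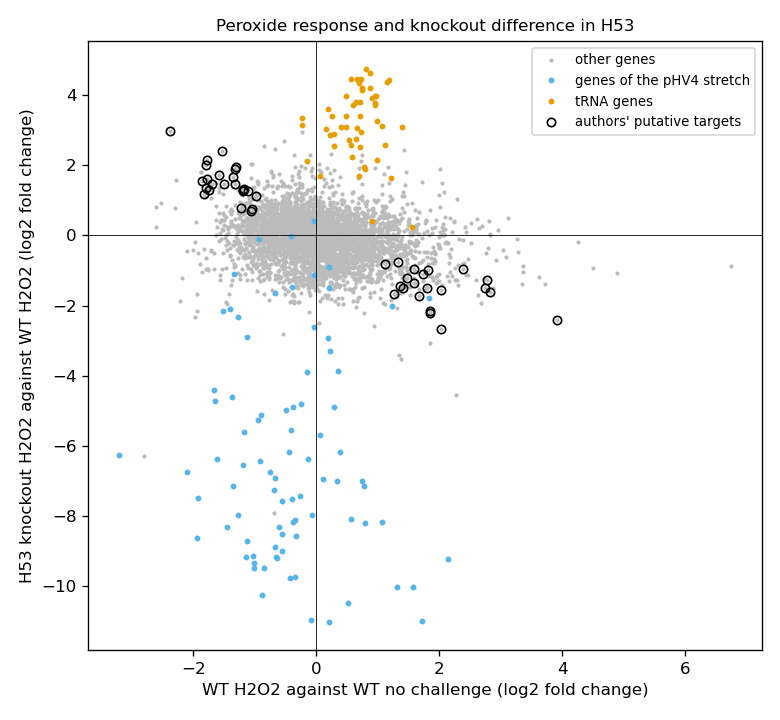
Log2 fold change with peroxide in the wild type (n = 5 and 4) against log2 fold change of the H53 knockout under peroxide (n = 4 and 5), 1 point per tested gene. The authors' putative targets are circled, and tRNA genes and genes of the pHV4 stretch are coloured. Over all genes r = -0.0363.

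The authors' deposited table calls 321 genes higher and 405 lower in the knockout among 3324 entries, and holds none of the 559 pHV4 genes. Its fold changes correlate with those here at r = 0.853 over 3188 genes, and 680 of its 713 tested calls have the same sign, with 496 called here. The correlation is 0.999 with replicate 5 of the wild type out and without the term for library origin, a fit chosen after seeing the data, in which 713 of 713 have the same sign. Of the 45 putative targets, which were chosen on these samples and so are not independent, 41 pass with the authors' sign in the peroxide contrast, 40 in the knockout contrast and 39 in both.

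In the H98 knockout under peroxide 880 genes were higher and 949 lower than in the H53 wild type under peroxide (edgeR, adjusted p, n = 3 and 5). Amino acid synthesis was higher in 25 of 43 genes and lower in 2 (camera adjusted p = 1.69e-05; adjusted p = 0.789 with an estimated correlation). Members that rose include serA of serine synthesis (2.15 ± 0.18 SE, adjusted p = 6.2e-07), the glutamate synthase gene gltB (2.15 ± 0.26, 1.21e-05) and the glutamine synthetase gene glnA (2.10 ± 0.23, 6.15e-06). Genes that fell include tatAo (-3.25 ± 0.52), the ArcR regulator gene HVO_RS19590 (-2.85 ± 0.35) and sod (-2.58 ± 0.33, 2.1e-05); without replicate 5 of the wild type tatAo is at -1.71. The trpA gene, deleted in H53 only, was higher by 3.98 ± 0.60. This contrast holds the parent strain and the knockout together.

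Further amino acid synthesis genes that rose are leuB (1.82 ± 0.28), leuD (1.79 ± 0.40), lysA (1.60 ± 0.26), ilvD (1.60 ± 0.23) and argH (1.56 ± 0.27). Other genes that rose are the aminotransferase gene HVO_RS00335 (3.63 ± 0.20), the hydrolase gene HVO_RS03380 (2.32 ± 0.29), the mevalonate kinase gene mvk (1.56 ± 0.22), the transporter genes HVO_RS01070 (1.60 ± 0.33), HVO_RS07270 (1.58 ± 0.28) and HVO_RS07260 (1.19 ± 0.26), and the mismatch repair gene mutS at HVO_RS14005 (1.21 ± 0.23). The nickel regulator gene nikR (-2.50 ± 0.23), eif1A (-2.24 ± 0.28), the glycerol kinase gene glpK (-1.98 ± 0.25), HVO_RS09110 (-1.75 ± 0.27), secD (-1.69 ± 0.36; -0.72 without replicate 5 of the wild type), HVO_RS09745 (-1.68 ± 0.24), radA (-1.59 ± 0.27), HVO_RS12280 (-1.57 ± 0.19), HVO_RS01525 (-1.39 ± 0.28), the malic enzyme gene HVO_RS16435 (-1.06 ± 0.21) and cas6 (-0.81 ± 0.18) fell. The ArsR regulator gene HVO_RS08400 rose (1.08 ± 0.32, adjusted p = 0.0108), opposite to the H53 knockout; without replicate 4 of the wild type it is 0.80, which ends the call. The antioxidant list had 3 of 9 lower (0.150), and the tRNA list 4 of 53 higher and 19 lower, with a median of -1.35 (0.0994). With library totals alone the tRNA median is 0.91, below the median of 2.50 for coding genes in that fit.

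None of the 7 product-text lists passed camera in this contrast. The putative targets, chosen on these samples and so not independent, had 8 of 45 higher and 18 lower, 23 higher with library totals alone, and 9 and 20 over the list alone (adjusted p = 0.154); of these 22 have the authors' sign and 4 the opposite. The IntaRNA predictions had 8 of 25 higher and 6 lower (0.974), transporters 6 of 13 higher and 1 lower (0.314), and regulators 1 of 10 higher and 3 lower (0.314). Cobalamin had 2 of 5 higher and 1 lower (0.874), DNA repair 3 of 10 higher and 1 lower (0.548), and CRISPR-Cas 1 of 7 higher and 2 lower (0.800). The last 6 have the same counts over the list alone. With library totals alone 2411 genes are higher and 7 lower, the median coding log2 fold change is 2.50, and of the named genes called lower 13 turn positive, among them nikR, eif1A, radA and the malic enzyme gene.

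Genes changed in the same direction in both knockouts against the wild type numbered 182 higher (92.3 expected) and 430 lower (158 expected). The transporter genes HVO_RS07260 and HVO_RS07270 and pccA are among the higher genes, and nikR, eif1A, secD, tatAo, HVO_RS12280, HVO_RS19590 and HVO_RS09745 among the lower. The H53 knockout calls of secD and tatAo end without replicate 5 of the wild type, so neither is shared there. Because both contrasts use the same wild-type libraries, these were split between them after the data were seen, which gave 73 higher (47.8 expected) and 198 lower (64.7 expected). Over all genes r is 0.348 with a covariance of 0.516. In simulated unchanged groups r is 0.599, with a covariance lower than the observed one by 0.416. With the libraries split, r is 0.174 and the covariance 0.139. Without replicate 5 of the wild type 79 are higher and 164 lower, and without its replicate 4 there are 390 and 583. With library totals alone 1 is higher and 1 lower.

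**Figure D5:**
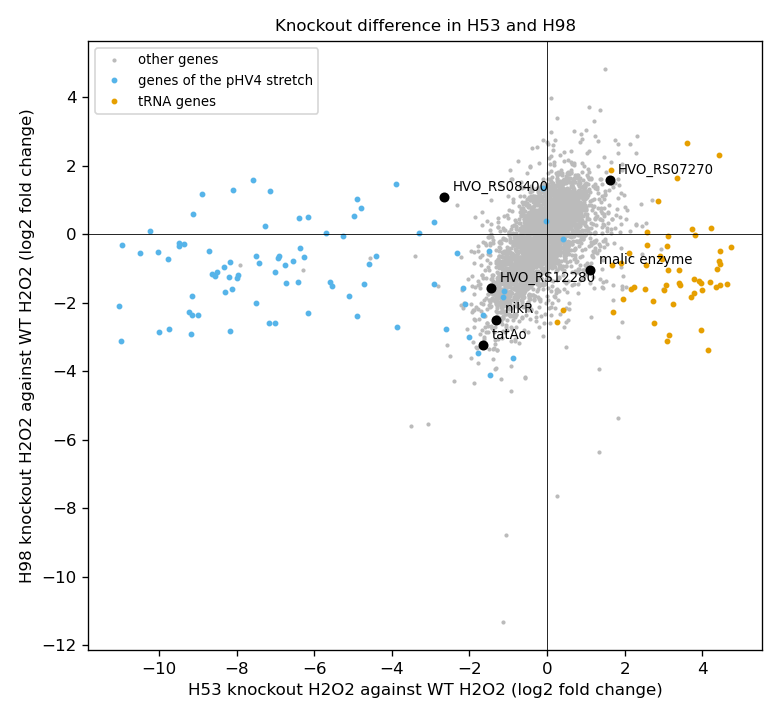
Log2 fold change of the H53 knockout (n = 4) against log2 fold change of the H98 knockout (n = 3), both relative to the same wild-type libraries under peroxide (n = 5), 1 point per tested gene. The malic enzyme gene, HVO_RS08400, tatAo, HVO_RS07270, HVO_RS12280 and nikR are marked. Over all genes r = 0.348.

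Between the knockouts 761 genes were higher in H98 and 724 lower (edgeR, adjusted p, n = 3 and 4). The ArsR regulator gene HVO_RS08400 was higher by 3.73 ± 0.32 SE (adjusted p = 4.42e-07) and gltB by 2.91 ± 0.23 (2.51e-07), while paaA (-3.04 ± 0.22, 1.77e-07), sod (-2.50 ± 0.31) and the malic enzyme gene HVO_RS16435 (-2.17 ± 0.20, 1.21e-06) were lower. All 10 phenylacetate and histidine genes were lower, though their median is 0.52 with library totals alone (camera adjusted p = 9.71e-11; adjusted p = 0.0135 with an estimated correlation), including paaB (-2.90 ± 0.36), paaC (-2.31 ± 0.27), paaD (-2.21 ± 0.30), hutU (-1.88 ± 0.26), hutI (-1.78 ± 0.25) and hutG (-1.71 ± 0.32). Amino acid synthesis was higher in 22 of 43 and lower in 1 (4.41e-05; adjusted p = 0.762 with an estimated correlation), with glnA (1.93 ± 0.20), serA (1.72 ± 0.16), lysA (1.71 ± 0.23) and ilvD (1.36 ± 0.20). The tRNA genes were lower in 51 of 53, with a median of -4.45, and -1.36 with library totals alone (6.85e-30; adjusted p = 0.461 with an estimated correlation).

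Single genes that differ between the knockouts include HVO_RS00335 (2.28 ± 0.17), HVO_RS03380 (1.98 ± 0.26), HVO_RS09720 (0.74 ± 0.18) and lrp (0.66 ± 0.15), which were higher in H98. The transporter genes HVO_RS00155 (-3.55 ± 0.58), arcD (-1.54 ± 0.32) and HVO_RS17705 (-0.94 ± 0.26), gdhB at HVO_RS11705 (-2.04 ± 0.24), the chemotaxis gene HVO_RS10585 (-1.81 ± 0.39), radA (-1.49 ± 0.25), HVO_RS19590 (-1.28 ± 0.32) and cas6 (-0.94 ± 0.16) were lower. The putative targets had 5 of 45 higher and 24 lower, 29 higher with library totals alone, and 5 and 26 over the list alone (camera adjusted p = 0.00152; adjusted p = 0.394 with an estimated correlation); the list was chosen on these samples and is not independent. Transporters had 4 of 13 lower (0.310), and of the 25 IntaRNA predictions 2 were higher and 5 lower (0.861), the same over each list alone. With library totals alone 3319 genes are higher and 28 lower, the median coding log2 fold change is 2.73, and 18 of the named genes called lower turn positive, among them the malic enzyme gene, hutU, radA and gdhB. With the pHV4 stretch as the term in place of library origin 792 of the 1485 calls stay (376 higher and 447 lower).

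No difference in the share of counts per replicon passed the adjusted threshold when all counts are used. The chromosome's share differed by -0.744 points with peroxide, 1.43 in the H53 knockout, -3.35 in the H98 knockout (exact permutation, adjusted p = 0.0571) and -4.78 between the knockouts, with pHV4 at 0.650, -0.938, 1.64 and 2.58. Without ribosomal and tRNA genes the chromosome's share rose by 1.51 points with peroxide, 2.25 in the H53 knockout (exact permutation, adjusted p = 0.0265 for both) and 2.28 in the H98 knockout (0.0397), while pHV4 fell by 1.49 in the H53 knockout (0.0265) and 2.27 in the H98 knockout (0.0397). With peroxide pHV3 fell by 1.19 points (0.0265) and pHV1 by 0.392 (0.0476). Counts without ribosomal and tRNA genes still hold signal recognition particle RNA and RNase P RNA. In replicate 5 of the wild type with peroxide these take 7.42% and 1.10% of all counts, against 8.27% for coding genes. In replicate 2 without challenge they take 1.07% and 0.336%, against 6.89%. Within the 4 numbered pairs of the peroxide contrast the chromosome's share rose by 1.39 points on average, at an exact p of 0.125, the smallest possible. In the same pairs pHV3 fell by 1.05 and pHV1 by 0.453, at the same exact p. None of the differences without ribosomal and tRNA genes passes the adjusted threshold over coding genes alone. The peroxide difference of pHV3 keeps its size there, at -1.07 points (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0794). Within the 4 numbered pairs pHV3 differs by -1.09 over coding genes (exact two-sided sign flips, p = 0.125). Over coding genes the chromosome's share differs by -0.315 points with peroxide for 5 against 4 libraries (exact permutation, adjusted p = 0.921). Within the 4 numbered pairs it differs by 0.827, with 3 pairs higher (exact two-sided sign flips, p = 0.25). The pairs leave out only replicate 5 of the wild type with peroxide, which has no numbered partner. The sign of this peroxide difference therefore depends on that library. In the knockouts the chromosome's share over coding genes differs by 2.77 in H53 and 4.11 in H98 (exact permutation, adjusted p = 0.0794 each). The share of pHV4 differs by -1.86 and -3.73 in the same order (0.0794 each). With the pHV4 stretch left out as well, pHV4 differs by -1.32 in the H53 knockout (0.106) and -3.71 in the H98 knockout (0.0816).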

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

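The tests of the pHV4 stretch, and those of gene length and of the H98 knockout for the tRNA genes, were chosen only after these results were seen. The splits of the libraries, the scaling test and the depth test were not.

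Other groupings of the same libraries were compared with the real ones. In the peroxide contrast 1 of 100 splits, the real one, gave as many calls as the real 1507, and the highest other gave 1198. This share, the smallest that 100 splits can give, argues against chance where the pairing is ignored. Only 12 splits part all 4 numbered pairs, the real one included, too few for a share under 0.05. The highest other among them also gave 1198, with replicate 5 of the wild type under peroxide placed among the unchallenged libraries. For the H53 knockout 2 of 100 splits gave at least the real 1034 calls, a share under 0.05, which argues against chance. The number of calls alone does not single out the real grouping, as another grouping gave more. The highest other gave 1198; it differs from the real one only in setting replicate 4 of the wild type beside the 4 knockout libraries. The next, with 325 and 314, also keep those 4 together, and splits that part them gave at most 64. For the H98 knockout 1 of 56 splits gave the real 1829 (highest other 1121). Between the knockouts 1 of 35 gave the real 1485 (highest other 517). Both shares are under 0.05, which argues against chance, but each is the smallest that its splits can give.

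Single libraries lie far from the rest of their group in 30 of 354 series of values, where 1 in 20 would give 17.7. The series are the named genes, count totals and shares in each group with at least 4 libraries. Many named genes were picked by contrasts that use these same libraries, so 17.7, which holds for unselected series, is no strict reference. Of the 30, 21 are in replicate 5 of the wild type with peroxide, which is the lowest in 17 and the highest in 4. Given as the gap to the nearest library over the range of the group, it is lowest for sufD (0.767), sufB (0.767), cas7b (0.729), cobJ (0.778), purQ (0.720), cobM (0.801), pccA (0.812), paaC (0.745), HVO_RS07260 (0.858), serS (0.8288), glyS (0.869), alaS (0.739), mutL at HVO_RS14000 (0.854), mutS at HVO_RS14005 (0.837), leuB (0.835), leuD (0.761) and argH (0.830). It is highest for nikR (0.798), secD (0.884), agl10 (0.719) and tatAo (0.905). Without this library 465 of the 1034 calls of the H53 knockout, 1397 of the 1829 of the H98 knockout and 1479 of the 1507 with peroxide stay. Its 5S ribosomal genes, both named rrf, take 9.88% and 9.63% of its counts, against at most 0.391% each in replicates 1 to 4 of the group. Why this library stands apart was not tested.

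The remaining cases are spread over other libraries. Replicate 1 of the unchallenged wild type has the highest coding share (0.944) and the lowest ribosomal share (0.933) of its group. Replicate 2 of that group is highest for cas1b (0.858), replicate 4 is lowest for HVO_RS03380 (0.870), and replicate 3 of the wild type with peroxide is highest for HVO_RS12280 (0.741). In the H53 knockout, replicate 3 has the lowest total (0.994), replicate 2 is lowest for HVO_RS08400 (0.915) and HVO_RS00065 (0.843), and replicate 1 is lowest for cas2 (0.973).

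The knockouts moved in opposite directions from the wild type for 62 genes, 16 of them tRNA genes and 46 coding, with the difference between the knockouts past the threshold in edgeR as well. The named ones are HVO_RS08400 (difference 3.73; -2.65 in H53 and 1.08 in H98), gltB (2.91; -0.76 and 2.15), paaB (-2.90; 1.53 and -1.37), the malic enzyme gene HVO_RS16435 (-2.17; 1.12 and -1.06) and hutU (-1.88; 1.04 and -0.84). Under library totals alone the differences of HVO_RS16435 (0.71) and hutU (0.56) turn positive, where the median coding difference between the knockouts is 2.73.

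In a stretch of 97 pHV4 genes 79 lie under 0.1 of their level elsewhere in 8 libraries. Low depth is argued against by an expected median of 30.4 counts per gene and library against 0 observed, and loss of the whole plasmid by a ratio of 0.884 for the pHV4 genes outside the stretch. A difference in processing between the reanalysed libraries and the rest is argued against because both kinds lie on both sides, with at least 2 libraries of either kind on either side. What stays open is that parts of the stretch may be absent from the DNA of these cultures. This would not cover the genes still counted there, such as HVO_RS02240 with 432 counts in the 8 libraries; no DNA data test this, and no biological explanation was tested.

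The tRNA genes have a median log2 fold change of 3.25 in the H53 knockout over the wild type under peroxide. Short coding genes, whose median lies -0.67 from that of longer ones (427 up to 300 bases, 3286 longer), do not share the rise. This cannot decide on a shorter insert range in those libraries, as the length of a coding gene does not set that of its fragments. Scaling is argued against by a median of 3.95 relative to coding totals. The H98 knockout does not show the rise in the main fit, with a median of -1.35. With library totals alone the median is 0.91, below the median of 2.50 for coding genes in that fit. The H98 knockout cannot decide on loss of SHOxi as the cause, as no H98 wild type was sequenced. A difference in how small RNA was kept during library preparation may remain, as no label records it, and the parent strains differ as well.

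More genes pass the threshold in the H98 knockout (1829) than in the H53 knockout (1034). Depth as the whole cause is argued against by thinning the H98 coding counts to 979127 per library, after which 1714 genes pass, 1.66 times the H53 number, and 1336 in place of 1485 between the knockouts. The parent strain differs as well and could account for part of the excess; this was not tested, since no H98 wild type was sequenced.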

How the results depend on the processing

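The alternatives that use the state of the pHV4 stretch, and those that leave out replicate 5 of the wild type with peroxide together with another change, were tests chosen only after the data were seen; so was the way the wild-type libraries were divided between the knockouts. Of the values compared under alternatives other than leaving out 1 library, 218 kept their direction and side of the threshold, or stayed within 1.5 times for counts, 44 moved, 9 passed the threshold only under the alternative, 5 no longer passed it and 8 reversed. Of 57 named genes called with peroxide, 1443 of 1539 comparisons kept the call and none reversed; for the H53 knockout 1066 of 1210 kept it and 1 reversed, for the H98 knockout 881 of 934 and 13, and between the knockouts 676 of 747 and 18. Scaling with DESeq2's size factors, dropping the filter, a stricter filter, DESeq2 and limma-voom left the numbers of genes called per contrast within 1.5 times. Depth limits the H53 groups most, with 378076 coding counts in the shallowest library. Alternatives for the 15 lists that were too small to test were not run. Where only 1 or 2 libraries remain in a group, their spread is taken from the other groups.

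With the replicate block the peroxide contrast has 936 genes higher and 872 lower, 1411 of the 1507 calls stay, and the calls of amino acid synthesis and tRNA genes change as given in the report, with no other list call changed. In the other contrasts not every correlation of same-numbered libraries is over 0.1, so by the rule fixed for it they share only a number. For the H53 knockout the correlations are 0.07, 0.06, 0.26 and 0.05, and 3 of 4 libraries correlate best with their own number, against 0 of 3 for the H98 knockout and 1 of 3 between the knockouts; this is a hint from the data, not the design. The replicate block gives 504 higher and 596 lower for the H53 knockout, without the calls of 4 of 45 named genes, 976 and 988 for the H98 knockout, and 852 and 819 between the knockouts.

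With library totals only, the numbers of genes higher and lower are 30 and 1 with peroxide, 11 and 69 in the H53 knockout, 2411 and 7 in the H98 knockout, and 3319 and 28 between the knockouts; converse genes are 0 and 0, and genes shared by the knockouts 1 and 1. Library totals, by construction, do not correct for the ribosomal share, which differs between the libraries. At an absolute log2 fold change of at least 1 the counts are 426 and 265, 197 and 416, 440 (higher only, H98) and 363 and 437, with converse genes at 90 and 24 and shared genes at 47 and 258, as fewer genes can pass. With the stretch term in place of library_set, the H53 knockout has 240 and 243, the difference between knockouts 376 and 447, converse genes 113 and 71 and shared genes 73 and 163; the cause was not tested. With replicate 5 out and the stretch term, 281 genes are lower in both knockouts. Smaller sets of libraries give fewer calls: libraries not reanalysed only, 294 and 197 with peroxide and 263 higher in the H53 knockout; libraries with counts in the stretch only, 360 and 269 with peroxide; libraries without, 483 lower with peroxide and 302 lower in the H53 knockout; reanalysed wild type only, 400 lower; the 2 groups alone, 217 higher. Split controls give 59 converse genes lower with peroxide, and 73 and 198 shared genes.

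Without 1 library in turn the counts run from 667 to 916 higher and 543 to 877 lower with peroxide, 233 to 640 and 265 to 810 in the H53 knockout, 722 to 944 and 773 to 968 in the H98 knockout, and 546 to 666 and 549 to 698 between the knockouts. Converse genes run from 122 to 267 and from 77 to 213, and shared genes from 79 to 390 and from 164 to 583. In the H53 knockout and for shared genes the lowest values are without replicate 5 of the wild type with peroxide and the highest without its replicate 4. Like all knockout libraries, replicates 4 and 5 are not reanalysed, while the rest of that group is. The term for library origin therefore gives them more weight than the rest in the knockout contrasts. Why they move the counts in opposite directions was not tested.

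With ribosomal and tRNA genes left out the differences in replicon shares change, as those genes lie on the chromosome: chromosome 1.51, 2.25, 2.28 and 0.0258 over the contrasts in order, pHV1 -0.392 with peroxide and -0.425 in the H98 knockout, pHV3 -1.19 with peroxide, and pHV4 -1.49, -2.27 and -0.787 in the last 3 contrasts. With all counts they were -0.744, 1.43, -3.35 and -4.78, pHV1 0.0775 and 0.378, pHV3 0.00250, and pHV4 -0.938, 1.64 and 2.58. Counts without ribosomal and tRNA genes still hold signal recognition particle RNA and RNase P RNA. Over coding genes alone, a test chosen only after the data were seen, the chromosome differs by -0.315, 2.77, 4.11 and 1.33, and no replicon passes the adjusted threshold. Within the 4 numbered pairs, which leave out only replicate 5 of the wild type with peroxide, the peroxide difference of the chromosome turns to 0.827.

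For the product-text lists, an estimated correlation ends the calls of cobalamin (0.148) and transporters (0.117) with peroxide, transporters and regulators in the H53 knockout (0.0571 each) and putative targets between the knockouts (0.394). With fry, adjusted p falls under the threshold for CRISPR-Cas (0.00657), regulators (0.000104) and IntaRNA predictions (0.0251) with peroxide, for transporters (0.0174), regulators (0.000409) and putative targets (0.00517) in the H98 knockout, and for transporters between the knockouts (0.0132). The cause was not tested.

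With library totals only, the median coding log2 fold change is 2.50 in the H98 knockout and 2.73 between the knockouts. Among named genes called in the analysis of the report, in the alternative or in both, direction reverses with library totals only, apart from HVO_RS08400 in the H53 knockout, at 0.0354 with both knockouts as 1 group. In the H98 knockout they are cbiG (1.97), nikR (0.15), HVO_RS01525 (1.23), cas6 (1.70), cas1b (1.58), eif1A (0.35), radA (0.82), HVO_RS09110 (0.79), HVO_RS09745 (0.90), glpK (0.57), HVO_RS12280 (0.93), secD (1.07) and HVO_RS16435 (1.42). Between the knockouts they are cbiG (2.11), cobM (2.18), cbiT (2.32), cas6 (1.71), cas7b (2.39), sod (0.20), HVO_RS03990 (1.84), paaC (0.41), paaD (0.48), hutI (0.65), hutG (0.75), hutU (0.56), radA (1.05), HVO_RS07260 (2.17), HVO_RS10585 (0.86), gdhB (0.93), ligA (2.14), arcD (1.25), HVO_RS16435 (0.71), HVO_RS17705 (1.85) and HVO_RS19590 (1.51).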

Other observations

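Some gene groups were not described above. In the wild type with peroxide the tests of symbol lists, written after the first fits, found no group change past the threshold for phosphate and phosphonate transport (2 of 11 genes lower; camera adjusted p = 0.347), thiamine synthesis (2 of 7 lower; 0.385), N-glycosylation (3 of 12 lower; 0.385), heme synthesis (2 of 6 higher; 0.603), isoprenoid synthesis (1 of 7 higher and 3 lower; 0.347) or ribosomal proteins (2 of 8 lower; 0.347). Isoprenoid synthesis had 3 of 7 genes higher in the H53 knockout (0.0527) and 5 of 7 in the H98 knockout (0.0659). The antioxidant genes, all higher with peroxide, had 2 of 9 lower in the H53 knockout (0.330) and 3 of 9 lower in the H98 knockout (0.150).

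Pseudogenes take a mean of 0.0710% of coding counts in the unchallenged wild type, 0.281% in the wild type with peroxide, 0.160% in the H53 knockout and 0.0843% in the H98 knockout.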
